A study of Mus musculus with 24 samples.

How the data were processed

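RNA was measured in 24 mouse liver samples that the labels place in 3 groups of 8, vehicle, vutiglabridin and semaglutide. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy column kit, libraries were made with Illumina's stranded TruSeq kit for mRNA, and paired-end reads came from a NovaSeq instrument. The deposited table holds 1 FPKM value (fragments scaled by transcript length and by the mapped fragments of the library) per gene and sample, made by the authors. HISAT2, StringTie and DESeq2 are named in the submitters' processing notes, and their versions, roles and order, the genome build and any gene filter are not given in the sources used here. The table has 14293 rows, all of them protein-coding Ensembl genes whose identifiers and symbols match GENCODE M21 on GRCm38. Coordinates below are from that annotation.

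FPKM divides by gene length and by the fragments of the library, so a few very abundant genes can shift the values of all others, and the values of near-identical genes depend on how shared reads were assigned. Members of multigene families (major urinary proteins, Cyp2a, Cyp2b, Cyp2c and Cyp4a genes, glutathione transferases, Serpina1, Orm, Acot and class II histocompatibility genes) are therefore uncertain as single genes. Counts were not used, but the low FPKM values lie on steps that 1 fragment makes, which gives each library's approximate depth. These steps, from genes with an exon length of up to 1500 bp, implied 14.3 ± 2.66 M (mega) fragments (SD, n = 8) in vehicle, 12.6 ± 2.89 in vutiglabridin and 10.7 ± 1.22 in semaglutide libraries. All low values used lay within 0.2 of a whole number of fragments, while a step 0.75 times the size left at most 3.85% of them there in any library. Each step was chosen for its fit to these same values, so that contrast largely follows from the choice and does not test the depth. Vutiglabridin replicate 7 had the fewest implied fragments, at 6.01 M.

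The semaglutide columns were written differently from the others. All 114344 of their cells have a trailing space and 2 fixed decimals, and no cell of the other groups has that space. Of the 3 symbols that occur on 2 rows, all 3 pairs hold identical values in the 8 semaglutide columns and none do in the other 16 samples. The second row of Aldoa is 1 of these, so its apparent change is not taken as a measurement.

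Values were taken as log2(FPKM + 1), and fold changes are on that scale, which understates the change of low genes. Genes with at least 0.5 FPKM in at least 8 samples were tested, which left 11562. One limma model (limma 3.58.1 in R 4.3.3, moderated test with a mean trend, 2-sided) was fitted to all 24 samples with the 3 groups and no other term, and its p-values were adjusted by the Benjamini-Hochberg method within each of the 3 comparisons, with 0.05 as the threshold. Gene lists, written before the data were examined, were tested with limma's camera at a preset correlation of 0.01 between genes and adjusted over lists. Of the 38 lists, 34 had at least 5 tested members, and the lists of neutrophil (3 tested), paraoxonase (3), adipocyte (2) and pancreatic acinar (0) genes did not. Members were counted with p adjusted over all genes tested and also adjusted over the list alone. Pon1, Pon2 and Pon3 were tested with 2-sided exact permutation tests over all splits of 8 and 8, adjusted over the 9 tests.

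The genes to be named were set by a rule before the data were examined. The rule takes the 8 largest and 8 lowest changes per comparison, among genes with adjusted p under 0.05 and a group mean of at least 1 FPKM. Per called list it takes the 4 members with the lowest p among those that changed in the direction of the call. Members taken this way share the list's direction by choice, and only the counts given for a list show members that went the other way. The rule also allows the member with the lowest p of a list that was not called. It always takes the paraoxonases and the 4 autophagy members with the lowest p. The text names a part of these genes, picked after their values were seen. Plin2, Mogat1, Cidec, Irs2, Ppargc1a and Gaa under semaglutide, and the Y-linked genes used in a test, lie outside the rule and were also picked then.

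Alternatives set before the data were examined were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 1 FPKM, rescaling to TPM, quantile normalization, median centring, a robust spread estimate, sample weights, only the 2 groups compared, the replicate number as a block, Wilcoxon tests, an estimated correlation or fry for lists, and each sample left out in turn. Added after the data were seen were the removal of trends with GC content and exon length in each library (splines with 5 degrees of freedom, also with the block), the omission of the 6 rows that share a symbol, attention to vutiglabridin replicate 7, and the overlap of the drugs' calls in unchanged groups and with the vehicle samples split. On simulated data for the vutiglabridin and vehicle comparison, 84% of 100 genes changed by 0.5 on the log2 scale and 100% of 100 genes changed by 1 were recovered among 11576 tested. Of those calls, 3.66% were unchanged genes, and with no simulated effect 0 of 11561 genes were called. For semaglutide against vehicle, a simulated GC trend alone gave 434 calls among 11586 genes, and 0 after the correction. That trend was a straight line in GC content, which the splines of the correction contain, so its removal was fixed beforehand. It does not show how well the correction removes the trends of the real libraries. These simulations drew the noise of each gene and library independently, without correlation between genes. Their rates may therefore not hold for the real libraries.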

Results

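Liver RNA was profiled in 24 samples from mice with nonalcoholic steatohepatitis (NASH), a fatty liver disease with inflammation and scarring. Each of the 3 groups, vehicle, vutiglabridin and semaglutide, held 8 samples. Vutiglabridin is a synthetic analog of glabridin, a flavonoid of licorice, and the series title presents it as an agonist of paraoxonase-2 that activates autophagy. Semaglutide is an agonist of the receptor for the gut hormone GLP-1. The labels give no mouse model, sex, dose, duration, diet or animal, so the p-values measure the spread between these samples, which may be technical. The deposited FPKM values implied 12.0 to 19.6 M fragments (M, mega) per vehicle library, 6.01 to 15.3 M per vutiglabridin library and 9.35 to 12.4 M per semaglutide library.

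The 3 groups occupied separate areas of the first 2 principal components, which held 24.8% and 20.4% of the variance. Semaglutide libraries stood apart from both others. In 194 genes all 8 semaglutide values lay above the other 16, against 35 genes for vehicle and 13 for vutiglabridin. Fold changes of semaglutide against vehicle followed gene properties, with a Spearman correlation across genes of −0.303 with GC content and 0.272 with exon length, while those of vutiglabridin against vehicle gave −0.0660 and −0.0155. Genes are not independent replicates, so no p is given for these correlations.

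**Figure D1:**
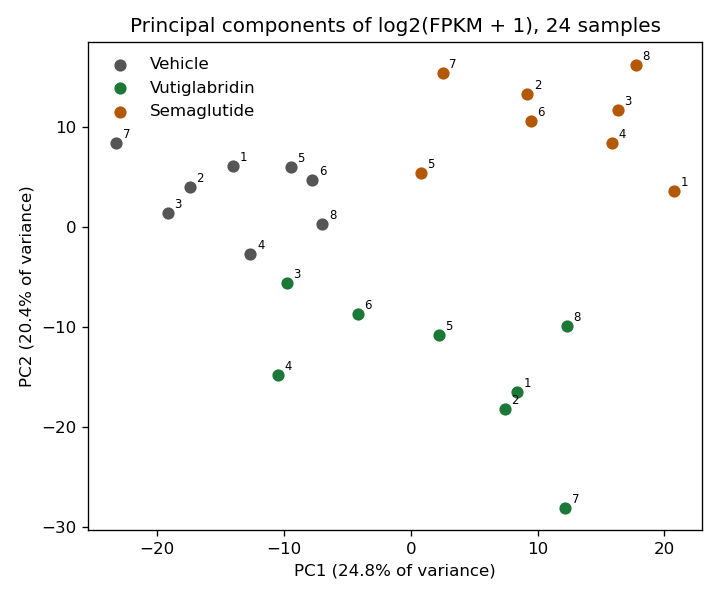
Samples on the first 2 principal components of log2(FPKM + 1). Each point is 1 sample, colored by group and numbered by replicate, and the axes give the share of variance (24.8% and 20.4%). Vutiglabridin replicate 7, the shallowest library, lies at the lower edge.

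The comparison of vutiglabridin with vehicle asks what the drug changed in the diseased liver. Genes of the scar matrix, of recruited macrophages, of antigen presentation and of the interferon response were lower in vutiglabridin livers, while genes of drug metabolism and cholesterol synthesis and male-biased liver genes were higher. Of the 21 gene lists called by camera at its preset correlation, 5 held with an estimated correlation, and the other 16 had adjusted p = 0.0574 to 0.601 there. Col1a1, which encodes a chain of type I collagen, fell from 20.1 ± 5.06 FPKM in vehicle (SD, n = 8) to 6.30 ± 3.39 in vutiglabridin (n = 8), a log2 change of −1.63 ± 0.22 (SE; limma adjusted p = 4.13e-05). Cyp2c29, a cytochrome P450 of drug and fatty acid metabolism, rose from 108 ± 24 to 473 ± 126 FPKM, a log2 change of 2.10 ± 0.16 (adjusted p = 6.68e-09). For both genes all 8 vutiglabridin values lay outside the range of the 8 vehicle values. Of 11562 genes tested, 1770 (15.3%) changed, 755 higher and 1015 lower, and 53 of them changed at least 2-fold. The values of the groups did not overlap in 201 genes, where chance gives 0.0155% of genes. FPKM totals were higher in vutiglabridin libraries (368614 ± 14580 against 330352 ± 14299, SD, n = 8), and rescaling to equal totals (TPM) moved the median log2 change of all genes from 0.01 to −0.13 and the calls to 2964, with 233 higher and 2731 lower.

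**Figure D2:**
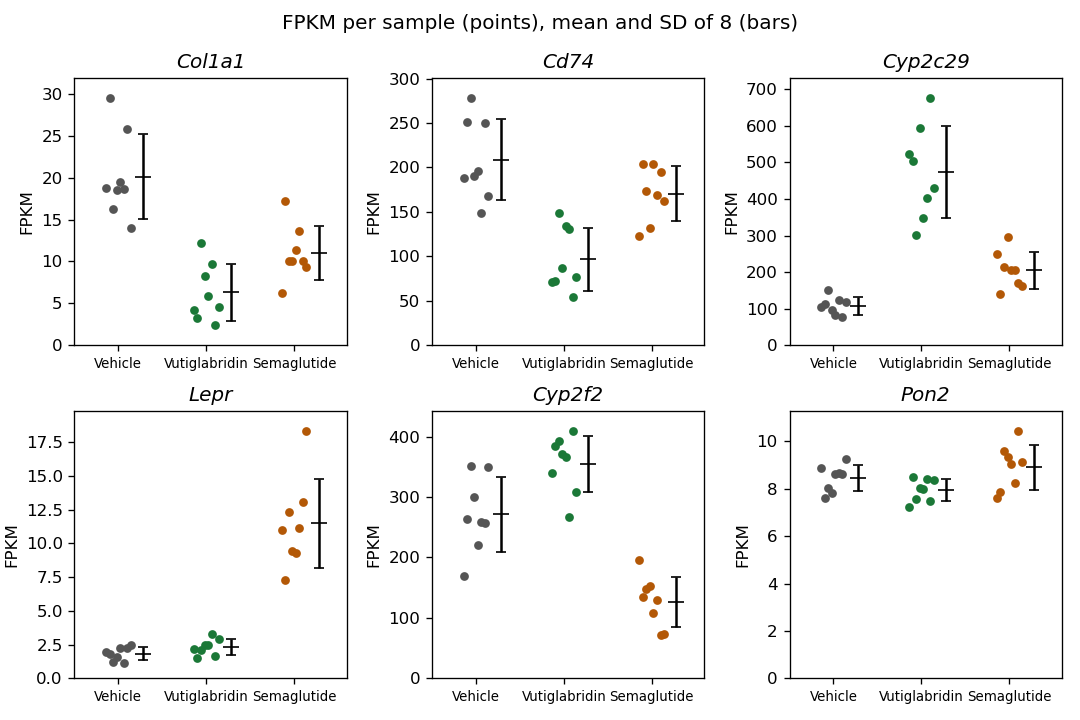
FPKM of 6 genes in each sample (points) with the mean and SD of 8 samples (bars), on linear axes from 0. Col1a1 and Cd74 are lowest in vutiglabridin, Cyp2c29 is highest there, Lepr is highest and Cyp2f2 lowest in semaglutide, and the Pon2 means lie between 7.95 and 8.90 FPKM.

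Matrix and fibrosis genes fell together in vutiglabridin livers. Of 36 tested members of this list, 29 fell, 0 rose and 7 did not pass (32 lower when adjusted over the list alone), with a median log2 change of −0.60 (camera adjusted p = 9.25e-24, and 0.0461 with an estimated correlation). Col3a1, Col1a2 and Timp1, an inhibitor of matrix-degrading enzymes, changed by −1.59, −1.31 and −1.40. Among the 8 lowest changes of the comparison were also Ubd, a ubiquitin-like protein induced by cytokines (−1.79), Anxa2 (−1.48), Sprr1a (−1.48) and Sdcbp2 (−1.44). Of 17 markers of hepatic stellate cells, which make scar matrix, 3 fell, 0 rose and 14 did not pass, 3 also when adjusted over the list alone (median −0.18, adjusted p = 0.0207). That call was lost at adjusted p = 0.487 with an estimated correlation, at 0.153 after TPM scaling (median −0.35) and at 0.0940 with no filter on low values (median −0.11). It was also lost at 0.141 without vehicle replicate 7, where the median was −0.08, and at 0.0521 and 0.0582 without vutiglabridin replicates 2 and 8.

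Immune genes were lower as well. Among markers of recruited and lipid-associated macrophages, 17 of 21 fell, 1 rose and 3 did not pass (18 lower and 1 higher adjusted over the list alone), with a median of −0.68 (adjusted p = 5.63e-12, and adjusted p = 0.109 with an estimated correlation). Ccr2, the receptor that brings monocytes into tissue, fell from 2.69 ± 0.509 to 1.07 ± 0.409 FPKM, and Cx3cr1 changed by −0.78. Of 12 genes of dendritic cells and antigen presentation 9 fell and 3 did not pass, also adjusted over the list alone (median −0.60, adjusted p = 2.09e-09, and adjusted p = 0.1 with an estimated correlation). Cd74, the chaperone of class II molecules, fell from 209 ± 45.5 to 96.9 ± 35.5 FPKM, and H2-Aa, a class II chain, changed by −1.12. The median of that list was −1.05 with a pseudocount of 0.1, −1.03 with a mean of at least 1 FPKM and −0.98 under TPM. Interferon response genes fell in 23 of 31 members with 0 higher and 8 not passing (24 lower adjusted over the list alone; median −0.44 and −0.70 under TPM, adjusted p = 3.66e-16, and 0.0438 with an estimated correlation), and Usp18 and Oasl2 changed by −1.06 and −0.64. Of 26 cytokine and chemokine genes 10 fell and 16 did not pass (16 lower adjusted over the list alone; median −0.39, adjusted p = 5.97e-08, and adjusted p = 0.126 with an estimated correlation). In that list, Ccl2 and Cxcl16, which attract monocytes and T cells, changed by −0.97 and −0.68, and the median was −0.61 with a pseudocount of 0.1 and −0.63 under TPM.

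Lymphocyte markers were lower too, at low levels. Of 8 tested T and NK cell markers 4 fell and 4 did not pass (5 lower adjusted over the list alone; median −0.34, adjusted p = 0.00125, and adjusted p = 0.197 with an estimated correlation). The median was −0.92 and −0.52 with pseudocounts of 0.1 and 0.5, −0.69 under TPM, −0.22 under quantile normalization and −0.16 with no filter on low values, and the list was called in all 5. Nkg7, a granule gene of cytotoxic cells, fell from 2.02 ± 0.973 to 0.946 ± 0.564 FPKM (adjusted p = 0.0359). Its adjusted p was 0.0758, 0.0745, 0.0511 and 0.0595 without vehicle replicates 3, 4, 7 and 8, and 0.0698, 0.0824 and 0.0785 without vutiglabridin replicates 1, 7 and 8. Quantile normalization and sample weights also ended its call (0.0827 and 0.0962). Of 5 B and plasma cell markers 1 fell and 4 did not pass, also adjusted over the list alone (median −0.51, adjusted p = 0.0320). The B cell median was −0.88 with a pseudocount of 0.1 and −0.24 with no filter, with the list called in both. Its call was lost at adjusted p = 0.427 with an estimated correlation, 0.281 under TPM (median −0.84) and 0.0675 under quantile normalization. It was also lost without vehicle replicate 3, the highest sample by the list's score, where the median was −0.22 (0.109), at 0.0525 without vehicle replicate 7 and at 0.0517, 0.0521 and 0.0592 without vutiglabridin replicates 1, 2 and 3.

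Cell cycle genes fell in 15 of 24 members with 0 higher and 9 not passing (19 lower adjusted over the list alone; median −0.37, adjusted p = 1.56e-12, and 0.0438 with an estimated correlation). Mcm6, a subunit of the replicative helicase, fell from 3.36 ± 0.746 to 1.43 ± 0.448 FPKM. The cell cycle median was −0.83 with a pseudocount of 0.1 and −0.75 under TPM. Markers of cholangiocytes, the cells of the bile ducts, fell in 8 of 18 members and 10 did not pass (13 lower adjusted over the list alone; median −0.49, adjusted p = 4.92e-07, and adjusted p = 0.237 with an estimated correlation). Krt8, a keratin that hepatocytes also express, and Krt19 changed by −0.55 and −0.77. The call of Krt19 (adjusted p = 0.0234) was lost without vehicle replicate 3 (0.0521), vehicle replicate 7 (0.05005) or vutiglabridin replicate 1 (0.0564).

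Genes of drug and xenobiotic metabolism were higher in vutiglabridin livers. Of 30 members 17 rose, 1 fell and 12 did not pass (20 higher and 2 lower adjusted over the list alone), with a median of 0.37, and 0.23 under TPM (adjusted p = 2.91e-10, and 0.0358 with an estimated correlation). Ces2a, a carboxylesterase, rose from 52.2 ± 6.70 to 130 ± 15.3 FPKM (log2 change 1.30 ± 0.09, adjusted p = 5.57e-10), and Cyp2c37 and Cyp2c54 changed by 1.53 and 2.22. Male-biased targets of growth hormone rose in 8 of 20 members and 12 did not pass (13 higher adjusted over the list alone; median 0.53, adjusted p = 2.96e-06, and adjusted p = 0.235 with an estimated correlation). Mup7, a major urinary protein gene of this list, changed by 3.05, and its near-identical relatives Mup11, Mup17, Mup14 and Mup18, outside the list, by 3.29, 2.96, 2.54 and 1.89. All 5 were among the 8 largest increases and varied widely between samples (94.9 ± 72.0 FPKM for Mup11 in vutiglabridin and 7.79 ± 5.56 in vehicle). In the list, Hsd3b5, a steroid enzyme of male mouse liver, changed by 1.80, and Cyp7b1, an oxysterol hydroxylase, by 1.02.

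Cholesterol synthesis genes rose in 9 of 24 members with 0 lower and 15 not passing (12 higher adjusted over the list alone; median 0.42, adjusted p = 4.55e-07, and adjusted p = 0.326 with an estimated correlation). Tm7sf2, a sterol reductase, rose from 9.55 ± 1.33 to 21.3 ± 6.50 FPKM, and Ebp, a sterol isomerase, changed by 0.49. Of 23 genes of bile acid synthesis and transport 6 rose, 2 fell and 15 did not pass (8 higher and 2 lower adjusted over the list alone; median 0.17, adjusted p = 0.00363, and adjusted p = 0.112 with an estimated correlation). Slc10a1, the main bile acid uptake carrier, changed by 1.05 and Cyp27a1, a sterol hydroxylase, by 0.51. Lipogenesis genes rose in 6 of 24 members and 18 did not pass, also adjusted over the list alone (adjusted p = 0.0222, and adjusted p = 0.601 with an estimated correlation), and their median of 0.11 turned to −0.04 under TPM and −0.03 under quantile normalization. The lipogenesis call was lost under quantile normalization (0.71), with a mean of at least 1 FPKM (0.0505), without vehicle replicate 7 (0.0877, median 0.06) and without vutiglabridin replicate 1 (0.171, median 0.00). The median was 0.17 and 0.21 without vutiglabridin replicates 2 and 7.

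Hepatocyte genes were higher as deposited. Among secreted and identity genes of hepatocytes 14 of 28 rose and 14 did not pass (20 higher adjusted over the list alone; median 0.26, adjusted p = 7.56e-12, and adjusted p = 0.0574 with an estimated correlation). Hpd, an enzyme of tyrosine breakdown, rose from 779 ± 121 to 1142 ± 104 FPKM and Serpina1a, a protease inhibitor of plasma, changed by 0.42. Periportal hepatocyte genes, from the zone around the portal vein, rose in 5 of 15 members, fell in 1 and did not pass in 9 (8 higher and 2 lower adjusted over the list alone; median 0.29, adjusted p = 0.00677, and adjusted p = 0.370 with an estimated correlation). Pericentral genes rose in 6 of 18 and 12 did not pass (9 higher adjusted over the list alone; median 0.17, adjusted p = 0.00429, and adjusted p = 0.290 with an estimated correlation). Acute phase protein genes rose in 6 of 21 and 15 did not pass (7 higher adjusted over the list alone; median 0.30, adjusted p = 0.00866, and adjusted p = 0.601 with an estimated correlation). Oxidative phosphorylation genes rose in 8 of 45 and 37 did not pass (13 higher adjusted over the list alone; median 0.16 and 0.00 under TPM, adjusted p = 1.51e-08, and adjusted p = 0.326 with an estimated correlation). Sdhb, a subunit of complex II, changed by 0.26 and did not pass under TPM or quantile normalization (0.135 and 0.0912). Quantile normalization ended the calls of the hepatocyte (adjusted p = 0.142), periportal (0.511), pericentral (0.142), bile acid (0.511), acute phase (0.347) and oxidative phosphorylation (0.746) lists. Under TPM, which moved the median of all genes to −0.13, the medians of the first 5 were 0.11, 0.14, 0.07, 0.03 and 0.14, and under quantile normalization they were 0.06, 0.19, 0.13, 0.06 and 0.13. The acute phase call was also lost without vutiglabridin replicates 2 (0.0667) and 7 (0.133, median 0.17) and with sample weights (0.0981, median 0.20). By the score of that list, 4 of 8 vutiglabridin samples lay below the vehicle mean, and replicates 2, 4 and 7 lay highest, at 1.15, 0.658 and 1.67 on the log2 scale.

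Autophagy, the process named in the series title, showed small increases. Of 45 genes of the autophagy machinery 12 rose, 0 fell and 33 did not pass (15 higher adjusted over the list alone), with a median log2 change of 0.10 that turned to −0.03 under TPM. The list was called as deposited (adjusted p = 1.66e-05, and 0.0438 with an estimated correlation) and relative to the shifted median of all genes under TPM (adjusted p = 0.000781). Its mean score was above all vehicle samples in 8 of 8 vutiglabridin samples. Atg14, a subunit of the lipid kinase that starts autophagosomes, rose from 6.51 ± 0.410 to 8.05 ± 0.838 FPKM (log2 change 0.27 ± 0.06, adjusted p = 0.00261). Map1lc3b, an autophagosome membrane protein, changed by 0.28, and Ulk2, a kinase, and Atg9a, a membrane transporter, each changed by 0.29. Under TPM the 4 genes did not pass, with adjusted p of 0.0741, 0.129, 0.160 and 0.0813. The list of lysosomal genes was not called between vutiglabridin and vehicle. By its score 6 of 8 vutiglabridin samples lay below the vehicle mean, 2 of them below all vehicle samples, and 2 lay above the mean.

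Pon2, the gene of the named drug target, did not pass between vutiglabridin and vehicle. It was at 7.95 ± 0.470 FPKM in vutiglabridin and 8.45 ± 0.558 in vehicle, a log2 difference of −0.08 (95% interval −0.19 to 0.04, exact permutation p = 0.0752, adjusted p = 0.101), with 7 of 8 vutiglabridin samples below the vehicle mean. Under TPM, where the median of all genes was −0.13, the difference was −0.24 and passed (exact test adjusted p = 0.00490). Its neighbor Pon1, a paraoxonase secreted into plasma, rose by 27.1%, from 192 ± 19.3 to 245 ± 24.5 FPKM (log2 change 0.35, exact permutation p = 0.000777, adjusted p = 0.00350), in 8 of 8 samples. In limma its adjusted p was 0.00373, and 0.0950 under quantile normalization. Pon3 differed by 0.08 (18.9 ± 1.91 and 17.9 ± 1.70 FPKM, exact permutation p = 0.253, adjusted p = 0.28) and by −0.07 under TPM. The 3 genes lie side by side on chromosome 6 of GRCm38, Pon1 at 5168090 to 5193946, Pon3 at 5220852 to 5256286 and Pon2 at 5264147 to 5298455, all on the minus strand. Values are sums over whole genes and not over single exons or UTRs. Col1a1 lies on chromosome 11 at 94936224 to 94953042, Cyp2c29 on chromosome 19 at 39269405 to 39330713, Cd74 on chromosome 18 at 60803848 to 60812652 and Ces2a on chromosome 8 at 104734003 to 104741634.

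**Figure D3:**
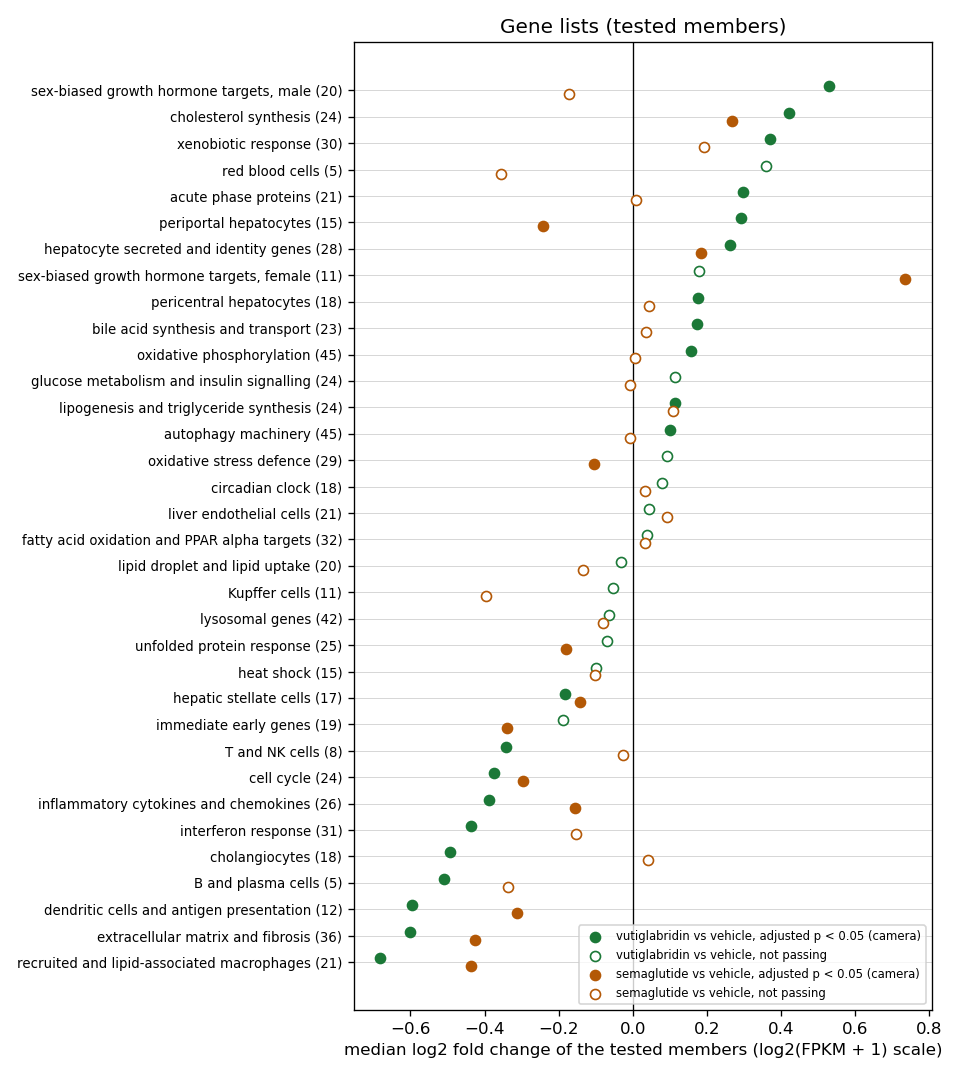
Median log2 fold change of the tested members of 34 gene lists (number of members in parentheses), for vutiglabridin (green) and semaglutide (orange) against vehicle. Filled points passed camera at adjusted p under 0.05 and open points did not. Medians of the autophagy and lipogenesis lists for vutiglabridin turn below 0 under TPM, that of lipogenesis also under quantile normalization.

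The comparison of semaglutide with vehicle asks the same of the second drug. The semaglutide columns were written differently, so a library or processing batch of their own cannot be told apart from the drug. Semaglutide livers had higher levels of the leptin receptor and of female-biased growth hormone targets, and lower levels of matrix, macrophage, cell cycle and immediate early genes. None of the 13 lists called by camera at its preset correlation held with an estimated correlation (adjusted p = 0.550 to 0.739). Lepr, the leptin receptor gene, rose from 1.82 ± 0.480 FPKM in vehicle to 11.5 ± 3.31 in semaglutide (SD, n = 8 each), a log2 change of 2.12 ± 0.14 (limma adjusted p = 7.15e-11). It lies on chromosome 4 at 101717404 to 101815352. Cyp2f2, a cytochrome P450 of periportal hepatocytes on chromosome 7 at 27119909 to 27133660, fell from 271 ± 62.1 to 127 ± 41.6 FPKM (−1.13 ± 0.17, adjusted p = 2.91e-05). Of 11562 genes 3124 (27.0%) changed, 1650 higher and 1474 lower, and 61 of them at least 2-fold. The groups did not overlap in 674 genes. Under TPM 1202 were higher and 2116 lower. With trends in GC content and exon length removed, 3288 genes changed, 2247 of them among the 3124 and in the same direction.

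**Figure D4:**
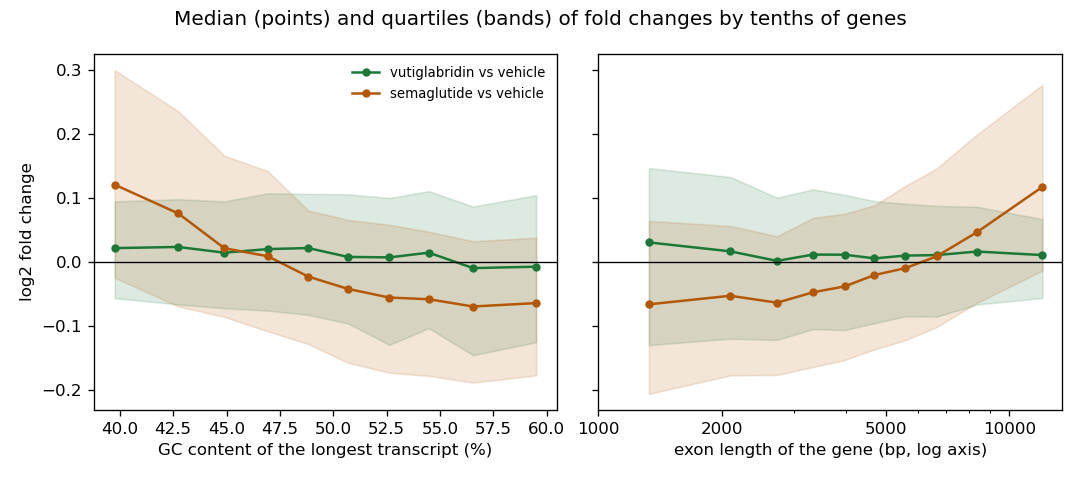
Median log2 fold change (points) and quartiles (bands) of genes in 10 equal bins by GC content (left, percent) and by exon length (right, bp, log axis), for vutiglabridin (green) and semaglutide (orange) against vehicle. Across genes, semaglutide fold changes fall with GC content (Spearman −0.303) and rise with length (0.272).

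Female-biased targets of growth hormone rose in 9 of 11 members, with 1 lower and 1 not passing, also adjusted over the list alone (median 0.74, adjusted p = 5.97e-05, and adjusted p = 0.550 with an estimated correlation). The list was called with the GC and length trends removed (adjusted p = 0.000398) and with no filter on low values, where the median was 0.39, and its score was above all vehicle samples in 8 of 8 semaglutide samples. Acot3, an acyl-CoA thioesterase, and Cyp2b9 changed by 1.95 and 1.90, and Abcd2, a peroxisomal transporter, rose from 4.73 ± 0.802 to 11.9 ± 3.24 FPKM. Other large increases were Cyp2a4, a cytochrome P450 of the xenobiotic list (1.85), Lars2, a mitochondrial tRNA ligase (1.80), Gprin3 (1.61) and Cyp4a14, a fatty acid hydroxylase (1.56). The largest value belonged to the second row of Aldoa (5.58), where semaglutide values repeat those of the other Aldoa row. Among the 8 lowest changes were Sdcbp2 (−2.24), Orm3, an acute phase protein (−1.99), Sprr1a (−1.99), Ly6d (−1.90), Cfd, complement factor D (−1.82), Sult1e1, estrogen sulfotransferase (−1.64), Cidea, a lipid droplet protein (−1.58), and Gsta1 (−1.56).

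Matrix and fibrosis genes fell in 22 of 36 members, with 1 higher and 13 not passing (24 lower and 2 higher adjusted over the list alone; median −0.42, adjusted p = 1.39e-07). Loxl2, a collagen cross-linking enzyme, Col5a2 and Postn changed by −0.64, −0.56 and −0.69. Recruited macrophage markers fell in 12 of 21, with 1 higher and 8 not passing (15 lower and 1 higher adjusted over the list alone; median −0.44, adjusted p = 2.88e-05). Lgals3, galectin-3, fell from 19.6 ± 7.11 to 8.25 ± 2.51 FPKM, and Trem2, a lipid receptor of macrophages, changed by −0.72. Of 12 antigen presentation genes 5 fell and 7 did not pass (9 lower adjusted over the list alone; median −0.31, adjusted p = 0.00548), and H2-DMb1 changed by −0.65. Cell cycle genes fell in 13 of 24 and 11 did not pass (15 lower adjusted over the list alone; median −0.30, adjusted p = 5.75e-06, and adjusted p = 0.735 with an estimated correlation). Mcm2 of the replicative helicase and Cdkn1a, an inhibitor of the cycle, changed by −0.40 and −1.16, and the list's median was −0.62 with a pseudocount of 0.1 and −0.54 under TPM. Immediate early genes fell in 8 of 19 and 11 did not pass (9 lower adjusted over the list alone; median −0.34, adjusted p = 0.00130), with Fos at −0.65 and Btg2 at −1.01. Apart from the cell cycle list, the lists of this paragraph had adjusted p = 0.739 with an estimated correlation, and all 5 were called with the GC and length trends removed.

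Cholesterol synthesis genes rose in 8 of 24 members and 16 did not pass (9 higher adjusted over the list alone; median 0.27, adjusted p = 0.00317, and adjusted p = 0.739 with an estimated correlation). The median was 0.17 without semaglutide replicate 2 (adjusted p = 0.0323). Stard4, a sterol carrier, changed by 0.74 and Tm7sf2 by 0.61. Secreted and identity genes of hepatocytes rose in 9 of 28 and 19 did not pass, also adjusted over the list alone (median 0.18, adjusted p = 0.00280, 0.739 with an estimated correlation and 0.0556 under quantile normalization, where the median was 0.10). Apob and Kng1, which encode plasma proteins, changed by 0.39 and 0.33, and Apob by 0.19 with the GC and length trends removed. With the GC and length trends removed both lists were called (0.00212 and 1.88e-05).

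A further 5 lists were called lower but did not pass once the GC and length trends were removed, and each had adjusted p = 0.739 with an estimated correlation. Their medians without the trends stayed below 0, smaller in 4 lists and larger for stellate markers. Periportal hepatocyte genes fell in 5 of 15, with 1 higher and 9 not passing, also adjusted over the list alone (median −0.24, adjusted p = 0.0331, and median −0.15, adjusted p = 0.102 without the trends), and Sds, serine dehydratase, changed by −0.89. The periportal call was also lost without vehicle replicates 6 (0.0554) and 8 (0.0570) and semaglutide replicates 2 (0.0732, median −0.11) and 5 (0.0515). Cytokine and chemokine genes fell in 7 of 26 and 19 did not pass (8 lower adjusted over the list alone; median −0.16, adjusted p = 0.0252, 0.0645 under TPM with a median of −0.25, and 0.0539 with a mean of at least 1 FPKM), with Vcam1 at −0.43 and Ccl6 at −0.84. Without the trends their median was −0.13 (adjusted p = 0.0594). It was −0.10 without vehicle replicate 7 and −0.23 without semaglutide replicate 7, and the list was called in both. Oxidative stress genes fell in 7 of 29, with 2 higher and 20 not passing (8 lower and 2 higher adjusted over the list alone; median −0.10, adjusted p = 0.0331, and median −0.07, adjusted p = 0.102 without the trends), and Gsta2 changed by −0.89. The oxidative stress median was −0.16 under TPM. That call was lost without vehicle replicate 1 (0.0541) and semaglutide replicates 2 (0.0766) and 8 (0.0572).

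Genes of the unfolded protein response fell in 6 of 25 and 19 did not pass (7 lower adjusted over the list alone; median −0.18, adjusted p = 0.0348, and median −0.12, adjusted p = 0.0855 without the trends), with the chaperone cofactor Sdf2l1 at −1.01. The adjusted p of that list was 0.0508, 0.0676 and 0.0583 without vehicle replicates 1, 3 and 6, and 0.0680, 0.0590, 0.0563 and 0.0563 without semaglutide replicates 2, 3, 7 and 8. Hepatic stellate cell markers fell in 4 of 17 and 13 did not pass, also adjusted over the list alone (median −0.14, adjusted p = 0.0348, and median −0.16, adjusted p = 0.0514 without the trends), and Dcn, decorin, changed by −0.38. The stellate call was lost under TPM (0.0645, median −0.22), with sample weights (0.0578), and without vehicle replicate 7 (0.111), semaglutide replicate 3 (0.0503) or semaglutide replicate 5 (0.0563).

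The autophagy list was not called under semaglutide. Of 45 members 9 rose, 3 fell and 33 did not pass, also adjusted over the list alone (median −0.01, adjusted p = 0.373). Rb1cc1 (0.61, and 0.35 with the GC and length trends removed), Ulk2 (0.33) and Epg5 (0.24) rose and Becn1 (−0.19) fell. Pon3 rose by 24.8%, from 17.9 ± 1.70 to 22.5 ± 1.51 FPKM (exact permutation p = 0.0001554, the smallest the design allows, adjusted p = 0.00140), with no overlap between the groups. Pon1 differed by 0.19 (220 ± 27.5 and 192 ± 19.3 FPKM), which passed the exact test (permutation p = 0.0250, adjusted p = 0.0450) and not limma (adjusted p = 0.0663). It passed limma under quantile normalization (0.0201) and without vehicle replicate 8 (0.0272) or semaglutide replicates 6 (0.0471) or 7 (0.0336). Pon2 was at 8.90 ± 0.942 FPKM against 8.45 ± 0.558, a difference of 0.06 (95% interval −0.05 to 0.18, exact permutation p = 0.28, adjusted p = 0.28), and −0.10 with the GC and length trends removed.

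The comparison of the 2 drugs asks where their liver profiles differ. A possible batch of the semaglutide libraries also enters it. Vutiglabridin livers had more of the male-biased and fewer of the female-biased growth hormone targets than semaglutide livers, higher periportal, xenobiotic and oxidative stress genes, and lower interferon and bile duct genes. None of the 14 called lists held with an estimated correlation (adjusted p = 0.267 to 0.768). Cyp2f2 was at 355 ± 47.1 FPKM in vutiglabridin and 127 ± 41.6 in semaglutide (SD, n = 8 each), a log2 difference of 1.54 ± 0.17 (limma adjusted p = 8.45e-07). Lepr was at 2.32 ± 0.596 and 11.5 ± 3.31 FPKM (−1.89 ± 0.14, adjusted p = 1.03e-09). Of 11562 genes 2826 (24.4%) differed, 1372 higher and 1454 lower in vutiglabridin, 56 of them at least 2-fold. The groups did not overlap in 393 genes. Under TPM 596 were higher and 2264 lower, with the median of all genes at −0.08. Fold changes of this comparison followed GC content (0.254 across genes) and exon length (−0.291), and 2058 of the 2826 calls passed in the same direction with these trends removed.

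Male-biased growth hormone targets were higher in vutiglabridin in 13 of 20 members and 7 did not pass (16 adjusted over the list alone; median 0.68, adjusted p = 2.67e-07). Female-biased targets were lower in 7 of 11 and 4 did not pass (8 lower and 1 higher adjusted over the list alone; median −0.66, adjusted p = 0.000135), in 8 of 8 samples by the list's score. Both had adjusted p = 0.267 with an estimated correlation and were called with the GC and length trends removed. The female median was −0.12 with no filter on low values, −1.37 with a pseudocount of 0.1 and −1.17 under TPM, and the list was called in all 3. Mup7, Hsd3b5 and Cyp4a12b of the male list differed by 3.05, 1.73 and 1.66, while Cyp2b9, Abcd2 and Acot3 of the female list differed by −1.93, −1.30 and −1.50. Further large differences were those of Mup11 (2.74), Mup17 (2.73), Mup14 (2.49), Mup12 (1.95), Cyp2a4 (−2.60), Mt2, a metallothionein (2.13), Serpina1e (1.86), Sult1e1 (1.82), Orm3 (1.81), Lars2 (−2.01), Gprin3 (−1.50) and A1cf, an RNA-binding cofactor of Apob editing (−1.31).

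Periportal genes were higher in vutiglabridin in 8 of 15 members and 7 did not pass (11 adjusted over the list alone; median 0.44, adjusted p = 1.21e-05, and adjusted p = 0.267 with an estimated correlation), with Sds at 1.43. Xenobiotic genes were higher in 15 of 30, lower in 4 and not passing in 11 (17 higher and 4 lower adjusted over the list alone; median 0.34 and 0.22 under quantile normalization, adjusted p = 0.000282, and adjusted p = 0.267 with an estimated correlation). Ces2a, Cyp2c29 and Cyp2b10 differed by 1.06, 1.19 and 1.25. Oxidative stress genes were higher in 14 of 29, lower in 2 and not passing in 13 (18 higher and 2 lower adjusted over the list alone; median 0.20 and 0.12 under TPM, adjusted p = 0.000173, 0.502 with an estimated correlation and 0.0776 under quantile normalization, where the median was 0.11). The glutathione transferases Gstm3 and Gsta2 differed by 1.59 and 1.13. Oxidative phosphorylation genes were higher in 14 of 45 and 31 did not pass (15 adjusted over the list alone; median 0.16, adjusted p = 3.71e-06, 0.657 with an estimated correlation and 0.520 under quantile normalization), with Cycs, cytochrome c, at 0.40 and Cox7c at 0.66. The oxidative phosphorylation median was 0.09 with the GC and length trends removed (adjusted p = 0.00490), 0.07 under TPM and 0.02 under quantile normalization.

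Interferon response genes were lower in vutiglabridin in 18 of 31, higher in 1 and not passing in 12 (20 lower and 1 higher adjusted over the list alone; median −0.33, adjusted p = 1.79e-07, and adjusted p = 0.267 with an estimated correlation). Usp18 and Parp14 differed by −0.71 and −0.54, and the median was −0.49 under TPM. Cholangiocyte markers were lower in 9 of 18 and 9 did not pass (13 lower and 1 higher adjusted over the list alone; median −0.45, adjusted p = 0.000292, and adjusted p = 0.655 with an estimated correlation), with Muc1, a mucin, at −0.82 and Cd24a at −0.86. With a pseudocount of 0.1 and under TPM the cholangiocyte median was −0.76 and −0.71, and that of matrix genes −0.39 and −0.40. Matrix genes were lower in 9 of 36, higher in 1 and not passing in 26 (15 lower and 2 higher adjusted over the list alone; median −0.25, adjusted p = 0.00174, and adjusted p = 0.768 with an estimated correlation). Col1a1 was at 6.30 ± 3.39 FPKM against 11 ± 3.25 in semaglutide (−0.81 ± 0.22), and Thbs2 differed by −0.50. Antigen presentation genes were lower in 5 of 12 and 7 did not pass, also adjusted over the list alone (median −0.26, adjusted p = 0.0134), with Cd74 at −0.87 and H2-Aa at −0.59, and adjusted p = 0.729 with an estimated correlation, 0.0555 under quantile normalization and 0.0541 with sample weights. The antigen presentation median was −0.50 with a pseudocount of 0.1, −0.44 with a mean of at least 1 FPKM and −0.46 under TPM. T and NK cell markers were lower in 3 of 8 and 5 did not pass (4 adjusted over the list alone; median −0.31, adjusted p = 0.0134, 0.502 with an estimated correlation, 0.0552 under TPM and 0.107 under quantile normalization). The T and NK cell median was −0.88 and −0.48 with pseudocounts of 0.1 and 0.5, −0.62 under TPM and −0.15 with no filter.

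Autophagy genes were higher in vutiglabridin than in semaglutide in 7 of 45, lower in 1 and not passing in 37, also adjusted over the list alone (adjusted p = 0.0134, and adjusted p = 0.267 with an estimated correlation). The median of 0.09 turned to −0.00 under TPM, and the call was lost there (0.0820) and under quantile normalization (0.176, median 0.05). Atg16l2, Atg101 and Gabarapl2 differed by 0.74, 0.39 and 0.35 and Rb1cc1 by −0.52, and by −0.29 with the GC and length trends removed. Acute phase genes were higher in 7 of 21 and 14 did not pass, also adjusted over the list alone (median 0.39, adjusted p = 0.0126, 0.768 with an estimated correlation, 0.193 under quantile normalization with a median of 0.21, and 0.0541 with sample weights). That call was lost without vutiglabridin replicates 2 (0.0673) and 7 (0.124, median 0.24), and Crp, C-reactive protein, differed by 0.43. Secreted and identity genes of hepatocytes were higher in 7 of 28, lower in 1 and not passing in 20, also adjusted over the list alone (median 0.11, adjusted p = 0.0126, and adjusted p = 0.729 with an estimated correlation), and Serpina1b differed by 0.42. Their median was 0.01 under TPM and turned to −0.04 under quantile normalization (adjusted p = 0.605), and the call was lost with the GC and length trends removed (median 0.04, adjusted p = 0.251). Under quantile normalization Crp and Serpina1b did not pass (0.0812 and 0.141).

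Pon2 was lower in vutiglabridin than in semaglutide by 0.14 on the log2 scale (95% interval of the difference −0.26 to −0.03), in 8 of 8 samples against the semaglutide mean. The exact permutation test passed (p = 0.0235, adjusted p = 0.0450) and limma did not (adjusted p = 0.0652). Limma passed under TPM (0.00840) and quantile normalization (0.0419) and without semaglutide replicates 1 (0.0259) or 2 (0.0409). With the GC and length trends removed its adjusted p was 0.943. The exact call was lost under median centring (0.0543) and with the GC and length trends removed, where the difference was 0.01 (0.922). It was −0.25 under TPM, where the call held. The call was lost without any 1 of vutiglabridin replicates 1, 3, 4, 5 and 7 and semaglutide replicates 3, 4, 5, 7 and 8, at differences of −0.14 to −0.11 (adjusted p = 0.0579 to 0.0850). It was also lost without any 1 of vehicle replicates 1 to 7 (0.0512 to 0.0528), which are not in this test and left the difference at −0.14, through the adjustment over the 9 tests. Pon3 was lower in vutiglabridin by 0.24 (exact permutation p = 0.00233, adjusted p = 0.00699), and Pon1 differed by 0.15 (exact permutation p = 0.0789, adjusted p = 0.101), by −0.04 under quantile normalization and by 0.21 with the GC and length trends removed, where limma passed (adjusted p = 0.0262).

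Both drugs were compared with the same 8 vehicle samples. Across genes their log2 fold changes had a Pearson r of 0.478. Simulated unchanged groups with a shared control group gave a mean of 0.496 (0.0426 to 0.722 in 100 simulations). That control group was drawn anew in each simulation from the libraries of all groups, and was not the vehicle group. The covariance was 0.0282 against 0.00527 simulated, a difference of 0.0229. With the vehicle samples split 4 and 4 over 70 splits, r was 0.386 on average (0.268 to 0.506), with a covariance of 0.0241. Fold changes had the same sign in 66.4% of genes, as in 66.4% of simulated ones, and in 61.1% with split controls. In both comparisons 229 genes rose, where independent lists would share 107.7, and 499 fell, where they would share 129.4. Unchanged groups against a control group drawn from the libraries of all groups shared 0 calls in 100 simulations. This leaves out the drugs' effects, as independent lists leave out the shared controls. Groups without an effect may have few calls to share, so a shared count of 0 is no baseline for the real counts. With the vehicle samples split, 60.8 genes rose and 173 fell in both on average (47 to 98 and 130 to 205), where independent lists would share 33.2 and 37.8. In opposite directions 29 genes were called, where independent lists would share 241 and unchanged groups shared 0. With split controls 11.8 genes were called in opposite directions on average (0 to 50), where independent lists would share 76.4.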

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

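The omission of the rows that share a symbol, the search for processing of its own and the removal of GC and length trends were tests chosen after the results were seen, while the splits of the samples were set before. Other splits of the samples argue against chance for the counts of changed genes, as far as 100 of the possible splits per comparison can tell. Of 100 splits of the vutiglabridin and vehicle samples only 1, the real one, gave as many as 1770, and the highest of the others gave 670. For semaglutide and vehicle only 1 of 100 splits, the real one, reached 3124 and the highest other gave 7. For the 2 drugs only 1 of 100, the real one, reached 2826 and the highest other gave 1522.

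Semaglutide libraries stood apart, with 194 genes above and 29 below all 16 other samples, where chance gives 0.0157 genes. The tables argue against GC content and length trends as the whole cause, since 164 genes were still above all others with the trends removed, more than 2 times the 31 of vehicle and 20 of vutiglabridin. Values copied between rows of one symbol touch only 6 rows, too few to account for the 194 genes. Without those rows 193 genes remained, an outcome that their small number fixed beforehand. A library or processing batch of its own for semaglutide could contribute and cannot be told apart from the drug, because all 3 pairs of rows with one symbol are identical in the 8 semaglutide columns alone and no other group shares that treatment. The drug itself stays open as the biological explanation.

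Single samples lay far from the other 7 of their group in 21 of 348 sets of 8 values. Far was judged by Dixon's ratio, the gap to the nearest value divided by the range. Its tabulated threshold is meant to be passed by chance in about 1 in 20 sets, a rate that was not checked here. Vutiglabridin replicate 7 had 1413 genes listed at 0 (156 to 424 in the others of its group) and an implied depth of 6.01 M (mega) fragments (12.0 to 15.3). In the same sample Cyp2b10 was at 7.60 FPKM (1.01 to 2.24) and Mup12 at 32.2 (3.40 to 8.69). In vutiglabridin replicate 3 Cyp27a1 was at 251 FPKM (292 to 333) and Hpd at 916 (1093 to 1252). Ly6d was at 31.5 FPKM in vutiglabridin replicate 8 (50.9 to 69.1), Map1lc3b at 11.8 in replicate 1 (14.4 to 16.1) and Parp14 at 2.95 in replicate 4 (3.56 to 4.14). Among vehicle samples, Atg16l2 was at 5.27 FPKM in replicate 4 (2.63 to 3.57), Cyp4a12b at 24.97 in the same sample (13.5 to 17.3), Cfd at 0.88 in replicate 6 (5.74 to 17.9) and Crp at 91.2 in replicate 7 (121 to 131).

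Among semaglutide samples, replicate 7 was far out for Cyp2b10, at 0.55 FPKM (0 to 0.21), Cyp2c54, at 6.12 (30.7 to 53.3), Gsta1, at 3.61 (0.30 to 1.31), and the second Aldoa row, at 68.7 (46.5 to 53.8). In replicate 1 Cd24a was at 3.43 FPKM (7.81 to 11.2) and Krt19 at 1.97 (3.76 to 5.89). Acot3 was at 2.73 FPKM in replicate 6 (9.32 to 18.5) and Cox7c at 75.5 in replicate 5 (32.8 to 47.4).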

How the results depend on the processing

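The removal of GC and length trends and the omission of rows that share a symbol were tests chosen after the results were seen, and the others were set before. For the genes the text names, which are a part of those the rule gives and were picked after their values were seen, 5619 values under an alternative kept their direction and their side of the threshold, 22 lost the call, 12 gained it and 6 reversed. Omitting a sample of the group not compared leaves fold changes as they were. Such values, here and for the lists, were almost sure to be kept. Of list results, judged by camera's direction and call, 1751 kept both, 69 lost the call and 1 reversed. The medians of the called lists were smaller by over 1.5 times in 46 of these values, larger in 35 and of the other sign in 5. Those 5 were autophagy under TPM (−0.0320 for vutiglabridin against vehicle and −0.00101 between the drugs), lipogenesis under TPM (−0.0446) and quantile normalization (−0.0272), and hepatocyte genes between the drugs under quantile normalization (−0.0372). For vutiglabridin against vehicle the count of changed genes was 1770 as deposited, 2964 under TPM, and from 1286 (without vehicle replicate 7) to 2025 (without vutiglabridin replicate 3) with a sample left out. For semaglutide against vehicle it was 2694 to 3362, and for the 2 drugs 2418 to 3154, with a sample left out. Quantile normalization gave 1386, 3316 and 2542 genes in the 3 comparisons. The TPM shift follows from its construction, since FPKM totals differ between the groups. The cause of the other changes was not tested.

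Lists called by camera numbered 21, 13 and 14 in the 3 comparisons, and 5, 0 and 0 with an estimated correlation. Those 5, for vutiglabridin against vehicle, were the autophagy, matrix, interferon, cell cycle and xenobiotic lists. With fry 17, 8 and 11 of the called lists held. Quantile normalization called 9 lists for the 2 drugs, 7 of them among the 14. Removing GC and length trends kept 21, 8 and 13 of the called lists.

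Same-numbered samples were not taken as paired, since the labels do not say what a number shares and not every pair had a correlation over 0.1. Correlations were −0.247 to 0.286, over 0.1 in 6 of 8 pairs of vehicle and vutiglabridin, 2 of 8 of vehicle and semaglutide and 3 of 8 of the 2 drugs, and 4 of 24 samples matched best with their own number. With the number as a block 1723, 3073 and 2748 genes changed, and all 21, 13 and 14 called lists held. The lists called with the block numbered 21, 14 and 16. With the block and the trends removed, 10 of the 13 semaglutide lists held, among them cytokines (adjusted p = 0.0385) and stellate markers (0.0381), which the removal of the trends alone had left at 0.0594 and 0.0514. With the block Pon1 for semaglutide passed limma (0.0453).

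Pon2 for vutiglabridin against vehicle was −0.235 under TPM, where the exact test passed, and −0.0962 to −0.0605 with a sample left out. Pon2 for semaglutide against vehicle was −0.104 with the GC and length trends removed, also with the block, and 0.0338 to 0.0924 with a sample left out. Between the 2 drugs Pon2 was −0.137 under median centring, 0.00829 with the trends removed, also with the block, and −0.170 to −0.112 with a sample left out. There 17 of 24 omissions ended the call, 7 of them of vehicle samples, which leave the difference as it was and act through the adjustment over the 9 tests. Pon1 between the 2 drugs was −0.0373 under quantile normalization, and Pon3 for vutiglabridin was −0.0734 under TPM. The correlation of the 2 drugs' fold changes was 0.431 to 0.511 with a sample left out (jackknife SE 0.0959). The shallowest library, vutiglabridin replicate 7, implied 6.01 M fragments and had 1413 genes listed at 0. How depth limits genes of different levels was not compared.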

Other observations

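The cell share, scaling, semaglutide batch and Y-linked gene tests below, and the removal of GC and length trends, were chosen after the results were seen, as were Plin2, Mogat1, Cidec, Irs2, Ppargc1a and Gaa. Several groups of metabolic genes moved in both directions under semaglutide without a call for the list. Lysosomal genes fell in 15 of 42 and rose in 4, with 23 not passing (17 lower and 5 higher adjusted over the list alone; median −0.08, camera adjusted p = 0.0705, and 1.66e-11 for a change in either direction by fry). The fry test in either direction, also used below, asks whether any members change, not whether they change more than other genes. Under semaglutide 27.0% of all genes tested changed, so its low p does not set these lists apart. Lamp1, a major lysosomal membrane protein, fell from 363 ± 9.81 to 283 ± 6.61 FPKM (SD, n = 8 each), while Gaa, the acid alpha-glucosidase, changed by 0.51. Lipid droplet genes fell in 7 of 20 and rose in 2, with 11 not passing, also adjusted over the list alone (median −0.13, adjusted p = 0.0747, and 8.10e-11 in either direction). Plin2, a coat protein of lipid droplets, fell from 254 ± 37.9 to 190 ± 33.3 FPKM, and Cidec and Mogat1 changed by −0.81 and −0.97. Vldlr, a lipoprotein receptor, rose to 1.70 ± 0.254 FPKM, a log2 change of 0.73.

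Genes of glucose metabolism and insulin signalling rose in 7 of 24 and fell in 3, with 14 not passing (7 higher and 4 lower adjusted over the list alone; median −0.01, adjusted p = 0.519, and 7.90e-10 in either direction). Insr, the insulin receptor, rose from 9.30 ± 0.981 to 14.1 ± 2.09 FPKM, and Irs2 and Ppargc1a changed by 0.53 and 0.40. Fatty acid oxidation genes rose in 7 of 32 and 25 did not pass, also adjusted over the list alone (median 0.03, adjusted p = 0.0840, and 0.0107 with the GC and length trends removed). Endothelial markers rose in 6 of 21, fell in 2 and did not pass in 13 (9 higher and 2 lower adjusted over the list alone; median 0.09, adjusted p = 0.0586), with Ptprb at 0.49. Kupffer cell markers fell in 4 of 11, rose in 1 and did not pass in 6 (5 lower and 1 higher adjusted over the list alone; median −0.40, adjusted p = 0.0747), with C1qb at −0.63. Under vutiglabridin Kupffer markers fell in 4 of 11 and 7 did not pass, also adjusted over the list alone (median −0.05, adjusted p = 0.153), with C1qb at −0.62, and endothelial markers rose in 2 of 21 and 19 did not pass, also adjusted over the list alone (median 0.04, adjusted p = 0.190), with Gpr182 at 0.30 and not passing under TPM (0.112).

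In vutiglabridin livers matrix, macrophage and antigen presentation genes were lower and hepatocyte genes higher, with adjusted p = 0.0461, 0.109, 0.1 and 0.0574 with an estimated correlation. A larger share of hepatocyte RNA that dilutes all other cells alike is argued against, since the endothelial minus macrophage score was 0.607 higher in vutiglabridin (exact permutation p = 0.0001554, the smallest the design allows, in 8 of 8 samples). The results of both lists were known when this test was chosen, so its p mostly restates them. The argument rests on their medians, 0.04 for endothelial and −0.68 for macrophage markers, where an equal dilution would lower both alike. The shallowest library is argued against as the cause, since 1438 genes changed and 20 of the 21 called lists held without it. The matrix, macrophage, antigen presentation and hepatocyte lists were among the 20. GC and length trends are argued against too, as their removal kept at least 96.7% of the matrix and macrophage medians. Scaling is argued against for the lower genes by medians under TPM, quantile normalization and median centring. They were −0.88, −0.59 and −0.59 for matrix, −0.87, −0.64 and −0.67 for macrophage and −0.98, −0.52 and −0.58 for antigen presentation genes. The highest camera adjusted p of the matrix and macrophage lists there was 1.15e-07. Camera compares a list with other genes, so a shift of all genes alike hardly alters that value. For the higher hepatocyte genes scaling cannot be told apart from the drug. Quantile normalization, which ended their camera call (adjusted p = 0.142), would also remove a true rise of the most abundant genes. Fewer macrophages and scar-forming cells, or lower expression in them, may both lie behind the lower genes, and bulk tissue does not separate these.

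Female-biased growth hormone targets were higher and male-biased ones lower in semaglutide than in vutiglabridin livers, both with adjusted p = 0.267 with an estimated correlation. Removal of GC and length trends kept at least 98.4% of both medians, which argues against those trends, and female mice among the semaglutide animals are argued against by the Y-linked genes Ddx3y and Eif2s3y, whose lowest ratio of a semaglutide library to the vehicle median was 0.875. A batch of the semaglutide libraries is argued against as the whole cause for the male-biased genes, since 77.2% of their median between the drugs was there between vutiglabridin and vehicle (score higher by 0.760, exact permutation p = 0.00140, with 8 of 8 samples above the vehicle mean and 5 of them above all vehicle samples), while for semaglutide against vehicle the median was −0.17 (camera adjusted p = 0.239). For the female-biased genes such a batch cannot be told apart from semaglutide, because the list was called against vehicle in semaglutide and not in vutiglabridin (camera adjusted p = 0.841), where 2 of 11 members rose, 2 fell and 7 did not pass (3 higher and 3 lower adjusted over the list alone; fry adjusted p = 0.00475 in either direction) and 5 of 8 samples scored above the vehicle mean, 4 of them above all vehicle samples, and 3 below the mean, 1 of them below all vehicle samples. A difference between the drugs in their effect on these genes stays open and was not tested otherwise.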
